A study of Mus musculus with 9 samples.

How the data were processed

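Gene expression was measured on Affymetrix mouse expression arrays in 9 samples of mouse forebrain, dissected at embryonic day 9.5 on a C57Bl/6 background. Per the labels, the samples are 2 wildtype, 3 Vegf120/188 and 4 Vegf188, and the isoform mice make only the VEGF isoforms in their name. Per the labels, the Vegf188 arrays form technical batch 1, and the wildtype and Vegf120/188 arrays form technical batch 2. Groups and replicate numbers were taken from the sample titles. The labels do not say whether a sample is 1 embryo or a pool, so p-values measure only the spread between these samples, which may be technical. The deposited tables also hold 18 columns of samples from other series, which were not used.

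The authors deposited a table of log2 signals adjusted between technical batches, per the file headers, and a matrix of log2 PLIER signals without that adjustment. The submitters' processing notes name Affymetrix Expression Console, PLIER and MAS5 without versions. The method of the batch adjustment is not stated. Log2 values of the series matrix equalled the deposited PLIER matrix, with a largest difference of 0. The authors kept 32063 of the 45101 probe sets in the adjusted table, by a filter that is not stated. The 27 columns of MAS5 detection values in the deposited matrix were not used, since their names do not match single samples of the labels. The authors also deposited a Z score per probe set for each genotype and a call of -1, 0 or 1, whose derivation is not stated.

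What the adjustment did was measured by comparing both tables over 32030 probe sets. It moved the means of the wildtype and Vegf120/188 groups by the same amount, with a largest change of their difference of 8.33e-09. It raised the SD within groups by a median factor of 1.38 in both of these groups and 1.17 in Vegf188. Over these probe sets, the median shift was -0.986 in wildtype and Vegf120/188 and 0.077 in Vegf188. Array medians over all probe sets of the unadjusted matrix except controls were 5.63 to 5.65 in batch 1 and 6.74 to 6.81 in batch 2. Over the probe sets kept in the adjusted table, they were 6.38 to 6.45 and 6.32 to 6.49 after the adjustment. These medians cover different probe sets, so their change mixes the filter with the adjustment.

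The adjusted log2 signals were analysed. The 33 control probe sets were left out, as were 604 probe sets with several gene symbols and 3404 with none. Of the 28022 probe sets with 1 symbol, 26428 matched a gene of the GRCm38.p6 gene table by Entrez number and took its symbol, and the others kept the symbol of the file. The table served only for names and for which genes neighbour each other. For the 6948 genes with more than 1 probe set, the brightest over the 9 arrays was used, which gave 15707 genes. Groups were compared with limma 3.58.1 in R 4.3.3, in 1 fit of all 9 arrays with 3 groups, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 and no fold minimum. The spread was pooled over the groups, since wildtype has 2 arrays. All adjusted p-values of single genes are from limma and 2-sided. The number of arrays limits the precision.

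The 22 gene lists, with 414 measured members, were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The lists covered VEGF ligands and receptors, cell types that forebrain tissue can hold, neighbouring brain regions, the cell cycle, hypoxia, Notch, matrix, axon guidance, immediate early and sex-linked genes. The comparisons, tests, lists and settings to vary were fixed before the data were examined, as was the rule for named genes. That rule allowed Vegfa, Flt1, Kdr, Nrp1 and Nrp2, up to 8 called genes per direction, the 5 genes with the smallest p in each direction where none was called, and up to 3 members per list with the largest moderated t. From the 70, 79 and 74 genes it allowed, the text names a part, by a criterion chosen after the values were seen. That part holds the VEGF genes, the called or smallest-p genes, 3 members of each called list, and the first member of another list where its unadjusted p was under 0.05. Trh, Id4, Fezf2, Msx2 and Sema6a in Vegf120/188 against wildtype, Wnt1 in Vegf188 against wildtype and En1 in Vegf188 against Vegf120/188 were added after their values were seen. Results of some genes that this criterion covers are not reported. Genes named with the authors' scores were also chosen after their values were seen.

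The steps were tested on simulated data built from the 15707 genes, with 100 genes changed at each size. In Vegf120/188 against wildtype, 69% of changes of log2 1 and 97% of changes of log2 2 were recovered, with 5 unchanged genes called. In Vegf188 against wildtype, the shares were 70% and 100%, with 15 unchanged genes called. In Vegf188 against Vegf120/188, they were 79% and 99%, with 10 unchanged genes called. An endothelial list shifted by log2 0.5 was called in each of the 3 comparisons, and 0 other lists were. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called by chance. The shift was also larger than the median difference of any list called in the data.

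Alternatives were the values without the batch adjustment, quantile normalization, median centring, leaving out the dimmest 40% of genes, the mean of a gene's probe sets, each probe set tested on its own, a fit of only the arrays compared, a trended and robust prior, array weights, a fold minimum of 1.5, an estimated correlation within lists, the replicate number as a block, and leaving out each array in turn. For Vegf188 against Vegf120/188, 1 alternative was added after the data were seen. It adds the sampling error of the mean of the 2 wildtype arrays to each standard error, which multiplies it by 1.36. For genes shared between the comparisons with wildtype, unchanged groups were simulated 20 times against the same wildtype arrays. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.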

Results

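Transcript levels were measured in forebrain microdissected from mouse embryos at embryonic day 9.5, on 9 arrays. VEGF-A is a growth factor for blood vessels, and splicing of Vegfa gives isoforms that differ in how strongly they bind heparan sulfate. The 3 groups were wildtype (n = 2), Vegf120/188 (n = 3), with no isoform other than those of 120 and 188 residues, and Vegf188 (n = 4), with the 188 isoform alone. Wildtype and Vegf120/188 were run in technical batch 2 and Vegf188 in technical batch 1. The log2 signals of pairs of arrays correlated across genes, which are not independent replicates, with r from 0.970 to 0.990. Spike-in controls averaged 3.61 to 3.88 in batch 1 and 7.83 to 8.58 in batch 2, in log2 signal before batch adjustment. The 3'-minus-5' difference of Actb, a sign of RNA or labelling quality, was 0.33 to 0.60 in batch 1 and 0.70 to 1.37 in batch 2. In Vegf120/188 replicate 1, Xist was at 1.59 and the Y-linked Ddx3y at 13.0, while Xist lay between 8.75 and 10.9 in the other arrays. Wildtype replicate 6 had the highest 3'-minus-5' differences of Actb (1.37) and Gapdh (0.40) of the 9 arrays, and lay at -20.1 on principal component 1, against 10.8 for wildtype replicate 5. In the 8 arrays without male signals, the Y-linked Eif2s3y lay between 1.27 and 4.92 and the Y-linked Ddx3y between 5.37 and 6.55. Signals in this low range, up to 6.55, are not shown to be above background. Among genes named below, all group means of Flt1, Dlx1, Fezf2, Robo2, Hoxb3, Olig2, Trp63, Hey2, Cdkn1a and Sema6a lay in it. The sizes of their differences are thus uncertain.

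Vegfa itself, the modified gene, was read by a pair of probe sets that gave different pictures. The brighter was at log2 7.50 ± 0.18 (SD, n = 2) in wildtype, 7.28 ± 0.35 (n = 3) in Vegf120/188 and 7.20 ± 0.23 (n = 4) in Vegf188. The dimmer was at 6.39 ± 0.34 in wildtype, 6.996 ± 0.055 in Vegf120/188 and 6.37 ± 0.11 in Vegf188. By limma on each probe set, the 1.52-fold higher signal of the dimmer Vegfa probe set in Vegf120/188 than in wildtype did not pass, with an adjusted p of 1.00 and an unadjusted p of 0.00602. The files do not say which part of Vegfa either probe set reads, so these values do not check which isoforms were made. The VEGF receptor genes Flt1, Kdr, Nrp1 and Nrp2 did not pass in any of the 3 comparisons. Nrp2 was the one with the largest difference, at log2 0.47 ± 0.22 (SE) higher in Vegf120/188 than in wildtype. That value rests on its brightest probe set, since 2 of its 3 probe sets were higher and 1 lower.

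**Figure D1:**
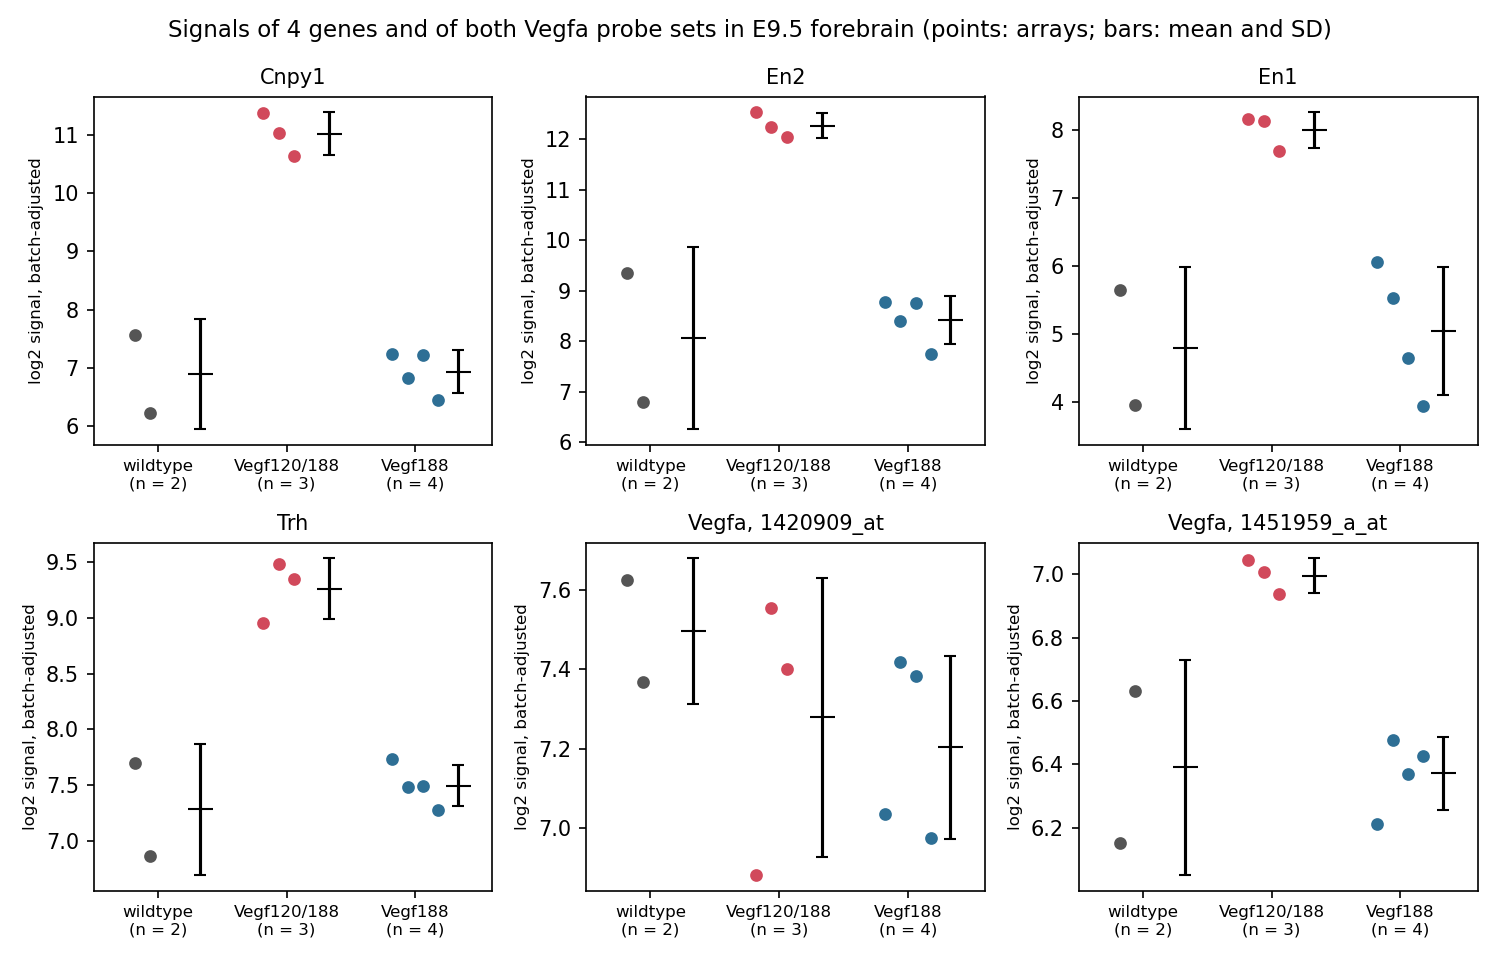
Batch-adjusted log2 signal (vertical axis) of Cnpy1, En2, En1, Trh and both Vegfa probe sets by group, with 1 point per array and a bar for the mean and SD. Cnpy1 lies between 10.6 and 11.4 in the 3 Vegf120/188 arrays and between 6.23 and 7.56 in the wildtype and Vegf188 arrays.

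Vegf120/188 forebrain was compared with wildtype within batch 2, to ask how loss of the remaining isoforms changes the tissue. Cnpy1, known from the midbrain-hindbrain boundary as a regulator of FGF signalling, rose 17.6-fold. Its log2 signal went from 6.89 ± 0.94 (SD, n = 2) in wildtype to 11.03 ± 0.37 (n = 3) in Vegf120/188, a difference of 4.13 ± 0.38 (SE; limma adjusted p = 0.00964), higher in 3 of 3 arrays. En2, the neighbouring gene and a homeobox factor of midbrain and anterior hindbrain, was 18.4-fold higher, at log2 4.201 ± 0.589, but did not pass over all genes (adjusted p = 0.151). Its relative En1 was 9.13-fold higher, at log2 3.19 ± 0.60 (adjusted p = 0.952), and Trh, which encodes the thyrotropin-releasing hormone precursor, was 3.95-fold higher (adjusted p = 0.0970). Both wildtype arrays lay below the 3 Vegf120/188 arrays for all 4 genes, though the wildtype pair itself was spread from 6.79 to 9.34 for En2. Both En1 values in wildtype (3.96 and 5.64) were in the low range, as was Cnpy1 in wildtype replicate 6 (6.23), so these folds are uncertain.

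Of the 22 lists, 3 were called, all higher in Vegf120/188 than in wildtype by camera with the preset correlation. Hypoxia and glycolysis genes had 24 of 26 members higher, with a median log2 difference of 0.27 (adjusted p = 9.16e-08, and 0.353 with an estimated correlation), among them the glycolytic enzymes Hk2 (0.45), Pkm (0.44) and Pfkl (0.43). Endothelial markers had 21 of 26 members higher, with a median of 0.16 (adjusted p = 1.52e-04, and 0.353 with an estimated correlation), among them Egfl7 and Ramp2 (0.37 each) and Plvap (0.41). Midbrain and hindbrain markers had 14 of 20 members higher, with a median of 0.15 (adjusted p = 0.0126, and 0.353 with an estimated correlation). Without wildtype replicate 5, the median of hypoxia and glycolysis genes was 0.11. Of the 3 Pfkl probe sets, 2 were higher and 1 lower, and of the 4 Egfl7 probe sets, 3 were higher and 1 lower. With an array left out, Ramp2 ranged from 0.09 to 0.66 and Plvap from 0.16 to 0.66. Fry called 0 lists, with a lowest adjusted p of 0.766. No member of the 3 lists passed over all genes, and 3 midbrain and hindbrain members, En2, En1 and Wnt1 (log2 0.90), rose when adjusted over the list alone.

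The other 19 lists did not pass in Vegf120/188 against wildtype, with adjusted p from 0.142 to 0.862. Their median log2 differences were 0.19 for pericyte and smooth muscle markers, 0.15 for sex-linked genes, 0.14 for primitive erythroid markers, and 0.13 for VEGF ligands and receptors and for neuronal differentiation. They were 0.12 for neural crest and mesenchyme markers, 0.09 for immediate early and heat shock genes, 0.04 for heparan sulfate and basement membrane genes and 0.02 for macrophage markers. Lower medians were those of dorsal forebrain patterning (-0.10), neural progenitor markers (-0.08), ventral forebrain patterning (-0.06), G2 and mitosis genes (-0.05), CDK inhibitors and p53 targets (-0.05) and axon guidance genes (-0.03). Surface ectoderm markers (-0.02), S phase genes (-0.02), eye and retinal pigment markers (-0.01) and the Notch pathway (-0.01) lay near 0. For ventral forebrain, surface ectoderm, S phase, CDK inhibitor and Notch lists, the median and mean were below 0 while the test, which compares with other genes, pointed up.

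Among forebrain regulators, values that did not pass were lower for Pax6, a factor of neural progenitors (log2 -0.70), Id4 (-1.11) and Fezf2 (-0.76). The Pax6 value rests on its brightest probe set, since 3 of its 5 probe sets were lower and 2 higher. Regulators with higher values that did not pass were the ventral forebrain factor Dlx1 (0.88), the neuronal factor Isl1 (0.65) and the dorsal midline factor Msx2 (0.62). The VEGF-C receptor gene Flt4 was at 0.41. Of guidance genes, Sema6a was at 0.78 and Robo2 at -0.69. Of the 3 Sema6a probe sets, 2 were higher and 1 lower, and its value ranged from 0.40 to 1.15 with an array left out. The pigment gene Tyrp1, with signals of 2.68 to 4.01 in the low range, was at -0.81, the mesenchyme factor Alx1 at -0.73, the S phase cyclin Ccne2 at -0.47 and the apoptosis gene Bax at 0.34. Each of these had a limma adjusted p of 1.00.

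Over all 15707 genes, limma called 1 gene, Cnpy1, in Vegf120/188 against wildtype, and 655 had an unadjusted p under 0.05, where 785 are expected by chance. The number under 0.05 was 291 with array weights, 862 with quantile normalization, 1141 without the batch adjustment and 1179 with a trended and robust prior. Whether it lay below or above chance thus depended on the processing. Limma called 7 genes with dim genes left out (En2 and Trh among them), 9 in a fit of the 2 groups (En2, En1 and Trh among them) and 12 with a trended and robust prior (Trh among them, En2 and En1 not). Cnpy1 missed the threshold with quantile normalization (adjusted p = 0.0588), the mean of its probe sets (0.135) or a trended prior (0.0695), and without wildtype replicate 6 (0.133), Vegf120/188 replicate 1 (0.0783) or Vegf120/188 replicate 2 (0.0702). The call of midbrain and hindbrain markers was lost with quantile normalization (0.119), median centring (0.173) and dim genes left out (0.111), and without wildtype replicate 5 (0.164) or Vegf120/188 replicate 1 (0.0854), and that of endothelial markers without wildtype replicate 6 (0.408, with a median of 0.09).

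Vegf188 forebrain was compared with wildtype to ask how the 188 isoform alone differs from the full set. The groups were in different technical batches, so batch and genotype cannot be told apart, and the values rest on the authors' adjustment. Neural lists were among those with lower values. All 16 neural progenitor markers had lower means in Vegf188, with a median log2 difference of -0.20, and 25 of 32 neuronal differentiation genes did, with a median of -0.24. Progenitor members with the largest statistics were Lhx2 (-0.88 ± 0.50 SE), Pax6 (-0.48 ± 0.22) and Sox9 (-0.37 ± 0.20), and neuronal members were Isl1 (-0.66 ± 0.26), the neurofilament gene Nefm (-0.81 ± 0.41) and Stmn3 (-0.51 ± 0.26).

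By camera with the preset correlation, 4 of 22 lists were called lower in Vegf188 than in wildtype. Neural progenitor markers had an adjusted p of 1.14e-04 (adjusted p = 0.525 with an estimated correlation) and neuronal differentiation 0.00150 (0.737 with an estimated correlation). CDK inhibitors and p53 targets were lower in 16 of 17 members, with a median of -0.16 and an adjusted p of 0.00628 (0.525 with an estimated correlation), among them the antiproliferative gene Btg2 (-0.41), the inhibitor Cdkn1b (-0.42) and Trp53inp1 (-0.40). The Notch pathway was lower in 15 of 19 members, with a median of -0.07 and an adjusted p of 0.0397 (0.737 with an estimated correlation), among them the receptor Notch2 (-0.33) and the targets Hey1 (-0.32) and Hey2 (-0.39). Fry called 0 lists, with a lowest adjusted p of 0.843, and 0 members of the 4 lists passed over all genes or adjusted over the list alone. These lists moved with wildtype replicate 6, where neuronal differentiation genes averaged 7.35 against 6.68 in wildtype replicate 5 and 6.59 to 7.08 in the Vegf188 arrays.

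The other 18 lists did not pass in Vegf188 against wildtype, with adjusted p from 0.159 to 0.863. Endothelial markers had a median of -0.03 and hypoxia and glycolysis genes of -0.000876. Higher medians were those of surface ectoderm markers (0.16), macrophage markers (0.12), pericyte and smooth muscle markers (0.11), immediate early and heat shock genes (0.05), VEGF ligands and receptors (0.01) and primitive erythroid markers (0.00448). Lower ones were those of sex-linked genes (-0.45), dorsal and ventral forebrain patterning (-0.13 each), S phase genes (-0.06), eye and retinal pigment markers (-0.05), G2 and mitosis genes (-0.03) and axon guidance genes (-0.02). For midbrain and hindbrain markers the median was 0.06 and the mean -0.16, and the test pointed up. For neural crest and mesenchyme markers the median (-0.00260) and the mean (0.09) also differed in sign, and for heparan sulfate and basement membrane genes a median of -0.02 stood against a test that pointed up. First members of lists that were not called were the macrophage gene Ptprc (0.82), the Wnt enhancer Rspo3 (-0.57), the ventral progenitor factor Olig2 (-1.08), the hindbrain factor Hoxb3 (-0.72), the epithelial factor Trp63 (-0.56) and the immediate early gene Jun (-0.37), and Wnt1 was at 0.57. With an array left out, Rspo3 ranged from -1.01 to -0.14 and Trp63 from -0.95 to -0.16. Ptprc signals were also in the low range, at 3.58 in wildtype and 4.40 in Vegf188. Each had a limma adjusted p of 1.00.

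No gene passed in Vegf188 against wildtype: limma called 0 of 15707, and 239 had an unadjusted p under 0.05, fewer than the 785 expected by chance. The smallest p-values among higher genes belonged to Cfhr2, a complement factor H relative (log2 1.23 ± 0.15; limma adjusted p = 0.0847), Vmn1r14 (1.62), Kpna7 (2.01), Ccdc83 (1.29) and Defb10 (1.60). The last 4 had mean signals of 1.99 to 2.96 in wildtype and 3.59 to 4.58 in Vegf188, not shown to be above background, so their sizes are uncertain. Cfhr2, with means of 5.08 in wildtype and 6.31 in Vegf188, was also in the low range. In the values without the batch adjustment, Cfhr2 (-2.09), Vmn1r14 (-1.80) and Kpna7 (-2.48) were lower in Vegf188 than the median of all genes, and Ccdc83 (-1.07) and Defb10 (-1.11) were close to it. There the median of all genes was at -1.05, 13530 genes were called and none of the 4 lists was. Among lower genes, the smallest p-values belonged to Tmem267 (-1.44 ± 0.21; adjusted p = 0.144), Id4, an inhibitor of basic helix-loop-helix factors (-1.37 ± 0.23; adjusted p = 0.283), Fn3krp (-0.62), Tshz2 (-0.60) and the forebrain factor Fezf2 (-1.05). Mean signals of Tshz2 (4.17 in wildtype, 3.57 in Vegf188) and Fezf2 (6.07 and 5.02) were in the low range, so their sizes are uncertain. Without wildtype replicate 6 none of the 4 lists passed (neural progenitor markers 0.0604 with a median of -0.08, CDK inhibitors and p53 targets 0.424 with a median of -0.04, neuronal differentiation and Notch pathway 0.770), and without Vegf188 replicate 2 or Vegf188 replicate 4 neuronal differentiation (0.0734, 0.0619), CDK inhibitors and p53 targets (0.0653, 0.0617) and Notch pathway (0.0734, 0.439) did not.

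**Figure D2:**
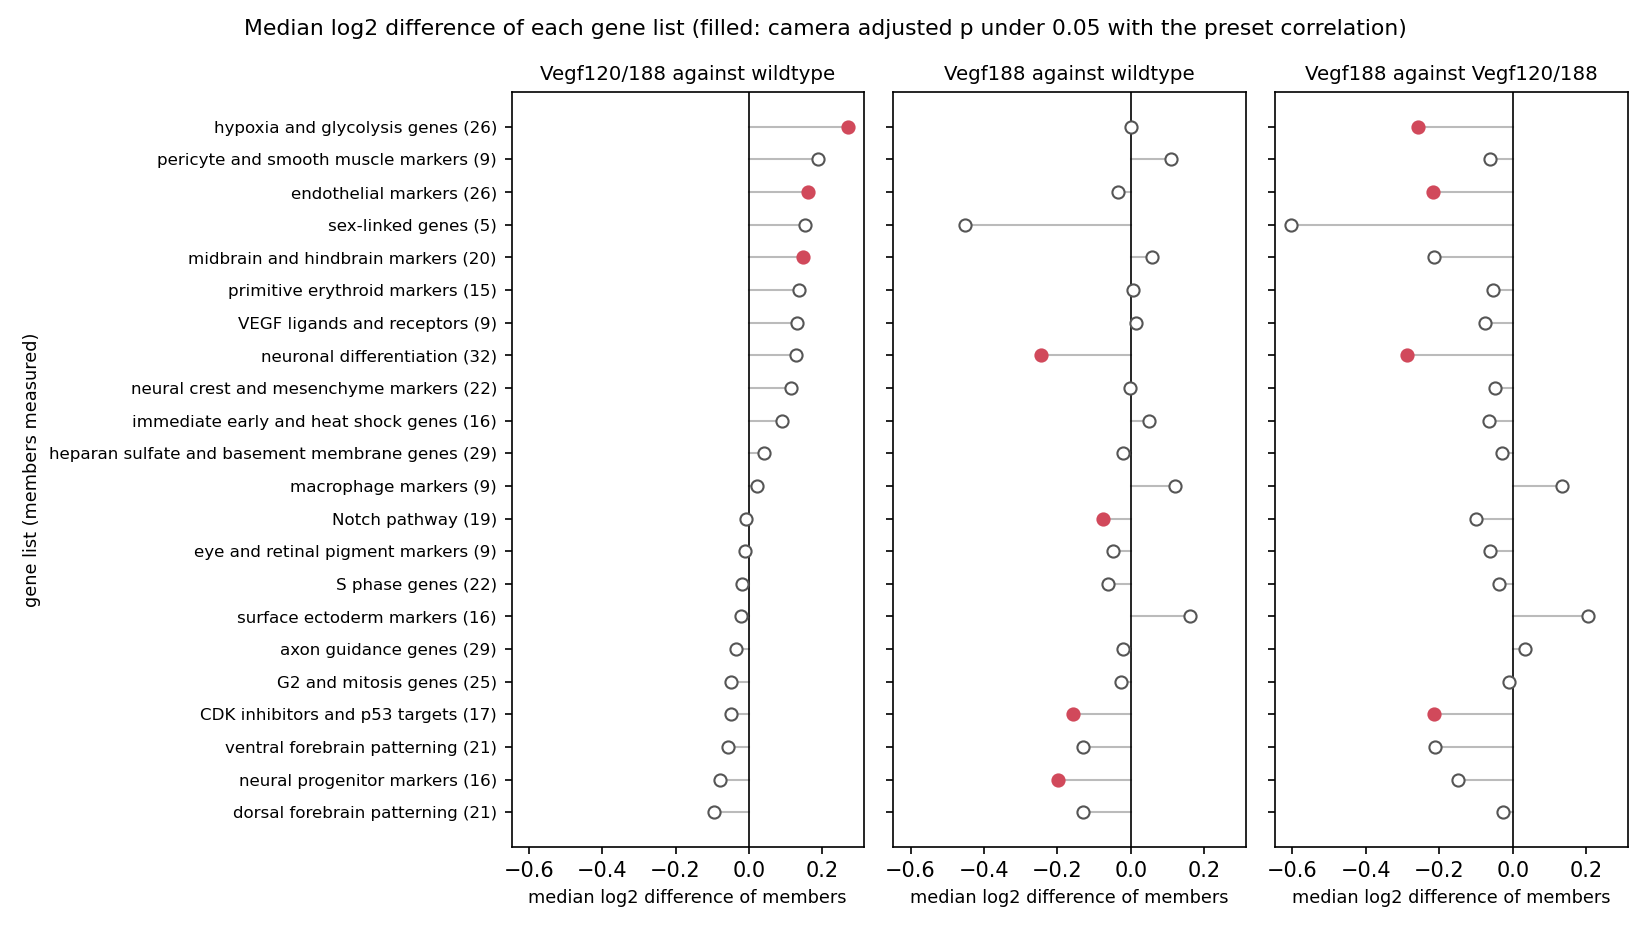
Median log2 difference of the members of each gene list (horizontal axis) in the 3 comparisons, with the measured members in parentheses. Filled points passed camera with the preset correlation, 3, 4 and 4 of the 22 lists, and 0 passed with an estimated correlation.

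Vegf188 was compared with Vegf120/188 to ask how forebrain with the 188 isoform alone differs from forebrain with the 120 and 188 isoforms. The amount of the 188 isoform was not measured and may differ between them, so presence of the 120 isoform cannot be separated from it. These groups too were in different batches, and batch and genotype cannot be told apart. Cnpy1 fell by 4.09 on the log2 scale in Vegf188 (SE 0.32; 17.1-fold lower; limma adjusted p = 0.00134) and En2 fell by 3.86 (SE 0.49; 14.5-fold; adjusted p = 0.0288), with Vegf188 levels close to wildtype after the authors' adjustment. Trh fell by 1.77 (SE 0.21; adjusted p = 0.0220), Tmem267 fell by 1.51 (SE 0.18; adjusted p = 0.0221), and Cfhr2 rose by 1.25 (SE 0.14; adjusted p = 0.0124). For each of these 5 genes the 4 Vegf188 arrays did not overlap the 3 Vegf120/188 arrays. All Cfhr2 values in these arrays (4.87 to 6.46) were in the low range, as were those of Tmem267 in Vegf188 (5.93 to 6.35). The size of these differences depended on the adjustment. Without it, where the median of all genes was -1.01, Cnpy1 differed by -1.25, En2 by -1.61, En1 by -1.36 and Tmem267 by -4.70. Trh (-0.68) and Cfhr2 (-2.07) turned relative to that median, as did, with these, 17 of the 36 genes chosen for this comparison. Of the 17, 13 were given as lower, among them Isl1, Eng, Esam, Crabp1, Bax, Btg2, Hk2 and Egln1. Against wildtype, the unadjusted Cnpy1 (2.88), En2 (2.59), En1 (1.83) and Trh (1.30) were higher in Vegf188, although the median of all genes was -1.05. Tmem267 rests on its brighter probe set, since the other differed by -0.02.

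By camera with the preset correlation, 4 lists were called lower in Vegf188 than in Vegf120/188. Hypoxia and glycolysis genes were lower in 24 of 26 members, with a median of -0.26 and an adjusted p of 4.74e-06 (adjusted p = 0.533 with an estimated correlation), among them the stress gene Ddit4 (-1.01), Hk2 (-0.49) and the oxygen sensor Egln1 (-0.46). Endothelial markers were lower in 22 of 26 members, with a median of -0.22 and an adjusted p of 5.33e-04 (0.533 with an estimated correlation), among them Eng (-0.42), the junction gene Esam (-0.30) and the VEGF-induced gene Esm1 (-1.66), whose signals of 1.00 to 3.94 are not shown to be above background. Neuronal differentiation was lower in 26 of 32 members, with a median of -0.29 and an adjusted p of 5.33e-04 (0.660 with an estimated correlation), among them Isl1 (-1.30; limma adjusted p = 0.0999), Nefm (-1.19) and the retinoid-binding gene Crabp1 (-0.67). CDK inhibitors and p53 targets were lower in 13 of 17 members, with a median of -0.21 and an adjusted p of 0.0374 (0.533 with an estimated correlation), among them Cdkn1a (-0.38), Bax (-0.35) and Btg2 (-0.35). Without the batch adjustment 0 lists were called, and the test pointed up for endothelial markers (adjusted p = 0.767), neuronal differentiation (0.609) and hypoxia and glycolysis genes (0.164). Adjusted over the list alone, 1 hypoxia and glycolysis gene and 2 neuronal differentiation genes fell, and 0 in the endothelial and CDK inhibitor lists. Fry called 0 lists in 1 direction, with a lowest adjusted p of 0.277, and 1 list in either direction, midbrain and hindbrain markers (adjusted p = 9.12e-04).

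The other 18 lists had adjusted p from 0.0634 to 0.879. The lowest of these belonged to midbrain and hindbrain markers, where 13 of 20 members were lower with a median of -0.22, 1 fell over all genes and 3 adjusted over the list alone. En1 was at -2.95 (limma adjusted p = 0.0907). Medians of the others were -0.60 for sex-linked genes, -0.21 for ventral forebrain patterning, -0.15 for neural progenitor markers, -0.10 for the Notch pathway and -0.08 for VEGF ligands and receptors. They were -0.06 for pericyte and smooth muscle markers and for immediate early and heat shock genes, -0.05 for primitive erythroid and for neural crest and mesenchyme markers, -0.04 for S phase genes and -0.03 for dorsal forebrain patterning and for heparan sulfate and basement membrane genes. Surface ectoderm markers (0.21), macrophage markers (0.13) and axon guidance genes (0.03) were higher. Eye and retinal pigment markers had a median of -0.06 while the test pointed up, and G2 and mitosis genes a median of -0.00948 and a mean of 0.02. First members of lists not called that were higher in Vegf188 were Ptprc (0.80), Alx1 (0.92), the eye and forebrain factor Otx2 (0.36), the proliferation marker Mki67 (0.43) and Robo2 (0.81), which rose when adjusted over its list alone. Lower values were those of Flt4 (-0.39), Dlx1 (-1.08), Msx2 (-0.62), Trp63 (-0.68), the Notch target Hey2 (-0.47), the heparan sulfate carrier Sdc4 (-0.62) and the chaperone gene Dnajb1 (-0.46). Xist was 4.23 higher in Vegf188 (limma adjusted p = 0.318), and 1.77 higher without Vegf120/188 replicate 1, where it passed (0.00578). The Vegf188 arrays (10.6 to 10.9) also lay above the wildtype arrays (8.75 to 8.98) for Xist.

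Over all genes, limma called 8 in Vegf188 against Vegf120/188, of which 4 were higher and 4 lower, and 3 of the 8 are known by clone or number alone. An unadjusted p under 0.05 was found for 1822 genes, where 785 are expected by chance. The count fell to 2 without Vegf120/188 replicate 3, 3 without Vegf120/188 replicate 1 and 5 without Vegf120/188 replicate 2, and to 2, of which Cnpy1 is the one with a gene name, when the sampling error of the wildtype mean was added to the standard errors. It was 0 with the replicate number as a block, 112 with array weights, 134 with dim genes left out, 368 with a trended and robust prior and 14010 without the batch adjustment. The call of CDK inhibitors and p53 targets was lost without Vegf188 replicate 1 (0.0507), 2 (0.104) or 4 (0.0730) and without Vegf120/188 replicate 3 (0.0885), and with quantile normalization (0.0545) or dim genes left out (0.129).

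Genes that moved in both isoform genotypes were sought in the 2 comparisons with wildtype. Limma called 0 genes in both, and groups simulated without an effect gave 0. With an unadjusted p under 0.05 in both, 15 genes had differences in the same direction, which does not show that they changed. They included Id4 and Fezf2, the forebrain factors Dach1 and Prdm16, and Rspo3, all lower, with 11 lower in total, and Wnt1 and the Wnt inhibitor Apcdd1, both higher, with 4 higher. Unchanged groups simulated against the same 2 wildtype arrays gave 264 such genes (range 225 to 296), and independent lists would give 5.10. The log2 differences of the 2 comparisons correlated across genes with r of 0.111 against 0.630 simulated (0.610 to 0.654). Their covariance was 0.00553 against 0.0448 simulated (0.0407 to 0.0476). Both observed values lay below the simulated ranges, so the simulation does not match these data. The 15 genes can thus not be read as fewer than chance would give. With 2 wildtype arrays the controls could not be split, and part of any overlap may come from them.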

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

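The test for an array far from the rest of its group was planned, and the genes it was run on are those chosen for the text. It was run on 66 genes, 22 lists and the median signal over the 4 Vegf188 arrays, 89 items in all. Of these, 3 passed, where about 1 in 20, or 4.45, are expected by chance. Groups of 2 and 3 arrays were not tested.

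Otx2 was at log2 9.73 in Vegf188 replicate 4 and 10.2 to 10.3 in the others, a gap of 0.883 of the range. Crabp1 was at 10.7 in Vegf188 replicate 1 and 11.1 to 11.2 in the others, a gap of 0.844 of the range. Ptprc was at 4.81 in Vegf188 replicate 3 and 4.198 to 4.296 in the others, a gap of 0.839 of the range. The 3 values came from 3 different arrays, and no explanation of them was tested.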

How the results depend on the processing

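Adding the sampling error of the wildtype mean was the 1 alternative chosen after the data were seen, and directions relative to the median were also chosen then. The alternative of another deposited signal, such as MAS5 signals, was not run, since the files hold none. Array weights and a trended prior were not run for lists.

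In Vegf120/188 against wildtype, limma called 2 genes without the batch adjustment (Cnpy1 and Trh), 0 with quantile normalization or the mean of probe sets, 7 with dim genes left out (6 higher, 1 lower), 9 in a fit of the 2 groups (6 higher, 3 lower), 12 with a trended and robust prior (8 higher, 4 lower, Cnpy1 not among them) and 3 of the probe sets. The count stayed at 1 with median centring, array weights or a fold minimum, and lay between 0 and 5 with an array left out. Lists called were 0 with an estimated correlation and 2 to 4 otherwise, as with an array left out.

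In Vegf188 against wildtype, 13530 genes were called without the batch adjustment (342 higher, 13188 lower, around a median of all genes of -1.05), 2 with dim genes left out (Id4 and Tmem267), 1 in a fit of the 2 groups, 5 with a trended and robust prior, and 0 to 1 with an array left out. Quantile normalization, median centring, the mean of probe sets, array weights, each probe set and a fold minimum gave 0. Lists called were 2 without the batch adjustment, both higher, 6 with dim genes left out (3 higher, 3 lower), 2 with the mean of probe sets, 0 with an estimated correlation, and 1 to 5 with an array left out.

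In Vegf188 against Vegf120/188, 14010 genes were called without the batch adjustment (253 higher, 13757 lower, around a median of -1.01), 134 with dim genes left out (54 higher, 80 lower), 368 with a trended and robust prior, 112 with array weights (63 higher, 49 lower), 30 of the probe sets, and 2 with the sampling error of the wildtype mean added, which widens every standard error 1.36-fold. Of the main 8 genes, 4 were among the 134, and all 8 among the 368 and the 112. Quantile normalization, median centring, the mean of probe sets, a fit of the 2 groups and a fold minimum gave 6 to 11. The count was 2 to 11 with an array left out. Lists called were 0 without the batch adjustment, 0 with an estimated correlation, and 3 to 7 with an array left out, 7 without Vegf188 replicate 3. Shared calls against wildtype were 2 without the batch adjustment, 1 with dim genes left out, and 0 with quantile normalization or with any array left out. For the counts that moved, the cause was not tested.

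With the replicate number as a block, 0 genes and 3 lists were called in Vegf188 against Vegf120/188. The numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.04, 0.02 and 0.01, and 0 arrays correlated best with their own number.

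By sign, which the common shift turns mostly for higher genes, directions reversed without the batch adjustment in Vegf188 against wildtype for Flt1 (-0.95), Cfhr2 (-2.09), Vmn1r14 (-1.80), Kpna7 (-2.48), Ccdc83 (-1.07), Defb10 (-1.11) and Ptprc (-1.84), and in Vegf188 against Vegf120/188 for Cfhr2 (-2.07), Ptprc (-1.86), Otx2 (-0.91), Alx1 (-1.49), Mki67 (-0.77) and Robo2 (-1.48). Against the other genes, the test also reversed for neuronal differentiation in both (-1.08 against wildtype, -1.19) and for endothelial markers (-0.89) and hypoxia and glycolysis genes (-0.84) in the latter. With the mean of probe sets, Vegfa in Vegf120/188 against wildtype (0.19), Flt1 (-0.0717) and Nrp1 (0.0554) in Vegf188 against wildtype and Nrp2 in Vegf188 against Vegf120/188 (0.25) reversed, and with quantile normalization Kdr in Vegf188 against wildtype (0.0198). Relative to the median of all genes without the adjustment, Flt1, Otx2 and Mki67 did not turn. In Vegf188 against wildtype 10 of 34 genes turned (6 given as higher, 4 as lower: Isl1, Hoxb3, Btg2 and Notch2), with Ccdc83, Defb10, Btg2 and Notch2 close to the median. In Vegf188 against Vegf120/188 17 of 36 turned, 4 given as higher and 13 as lower (Kdr, Nrp2, Trh, Eng, Esam, Isl1, Crabp1, Msx2, Bax, Btg2, Hk2, Egln1 and Dnajb1). The mean of probe sets and the omitted arrays change the values by construction, and for the rest the cause was not tested.

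With an array left out, signs reversed for VEGF genes, 1 other gene and 2 lists. In Vegf120/188 against wildtype, Nrp1 ranged from -0.10 to 0.24, Flt1 from -0.15 to 0.56 and Kdr from -0.0198 to 0.38. In Vegf188 against wildtype, Kdr ranged from -0.22 to 0.17, Nrp1 from -0.21 to 0.10, Flt1 from -0.22 to 0.50, Trp53inp1 from -0.82 to 0.0212, neuronal differentiation from -0.60 to 0.0851 and the Notch pathway from -0.26 to 0.02, the last 3 turning without wildtype replicate 6. In Vegf188 against Vegf120/188, Flt1 ranged from -0.12 to 0.00825, Nrp1 from -0.28 to 0.0436 and Vegfa from -0.27 to 0.0619. In Vegf120/188 against wildtype, Cnpy1 (3.47 to 4.80), En2 (2.93 to 5.48), En1 (2.35 to 4.03) and hypoxia and glycolysis genes (0.11 to 0.30) kept their direction. Cnpy1 was at -4.28 to -3.91 in Vegf188 against Vegf120/188. Without the batch adjustment it was at -1.25, close to the median of all genes of -1.01, or -0.25 relative to that median.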

Other observations

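The tests on the midbrain genes, on aligned wildtype means and on genes near Vegfa were chosen after the results were seen, and the splits of the arrays were planned.

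The calls in the authors' deposited table, made with a score whose derivation is not stated, were more numerous than those of limma on the 9 arrays. The authors' deposited table called 834 probe sets in Vegf120/188 (218 higher, 616 lower) and 116 in Vegf188 (55 higher, 61 lower), all with the sign of the differences measured here. In the authors' deposited table, the higher calls of Vegf120/188 included En2 (Z = 7.09), Cnpy1 (6.99), Id1, an inhibitor of differentiation (5.37), En1 (5.35) and the Wnt inhibitor Apcdd1 (5.07), besides the glycolytic genes Pkm and Aldoa, Dlx1, Msx2, Sema6a and the dimmer Vegfa probe set (4.71). Its lower calls in the authors' deposited table included Xist (-8.08), the lowest of all, Pax6 (-3.33), Ccne2 and the repellent Slit2. The Xist call and higher calls of the Y-linked Ddx3y and Eif2s3y in the authors' deposited table follow the 1 Vegf120/188 array with male signals. The Y-linked Kdm5d and Uty were also called higher there. Their brightest probe sets lay close together in the Vegf120/188 arrays (4.78 to 4.97 and 4.39 to 5.37), so the source of these calls is not shown. For Vegf188 the higher calls in the authors' deposited table included Cfhr2 (6.997), Xist (5.23), Apcdd1 (4.54) and the neuronal factor Lhx1 (3.65), and the lower calls Polh (-4.89), the hindbrain gene Hoxb1 and the mesenchyme factor Prrx1. Ddx3y and Uty were also called lower in Vegf188, although no Vegf188 or wildtype array used here had male signals. Endothelial markers had 0 calls in the authors' deposited table in either genotype.

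Cnpy1, En2 and En1 were 9.13-fold to 18.4-fold higher in Vegf120/188 than in wildtype, where En1 was in the low range and its fold uncertain. The batch adjustment is argued against as their source, since it changed no difference of means between these groups by more than 8.33e-09 and the smallest of the 3 was log2 3.19 (SE 0.64) before it, and the array with male sex-linked signals by the values without it, where the smallest was 3.11 (SE 0.69). A candidate explanation is more midbrain tissue in the Vegf120/188 pieces, but the other 18 midbrain and hindbrain markers had a median difference of 0.11 (95% bounds -0.05 to 0.35, with 12 higher and 6 lower), far below the change to be explained, so they give it no support. It is not excluded, since hindbrain members need not follow and members with forebrain expression hide a small share. A change by genotype also stays open, as do low values in the 2 wildtype arrays: without the batch adjustment Cnpy1, En2 and En1 were higher in Vegf188 too (log2 2.88, 2.59 and 1.83), which the adjusted values (0.04, 0.34 and 0.24) do not show.

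Small p-values were many in Vegf188 against Vegf120/188 (1822 genes under 0.05) and few in Vegf188 against wildtype (239), where 785 are expected by chance. The authors' adjustment may have aligned the wildtype means of both batches, so that the Vegf188 values are in effect set against wildtype arrays of batch 1 that are not analysed here. The covariance of the 2 comparisons with wildtype was 0.00553 but follows from the spread of the 3 comparisons, which is the pattern itself, so it decides nothing, and both this explanation and a difference between the genotypes stay open. If the wildtype means were aligned, differences in Vegf188 against Vegf120/188 carry a further sampling error of wildtype means. Adding that of the 2 wildtype arrays, which widens every standard error 1.36-fold and so does not test the explanation, left 2 of the 8 genes and 628 with an unadjusted p under 0.05.

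Of the genes within 50 places of Vegfa in gene order, 10 held a call in the authors' deposited table in either genotype, where the median of windows elsewhere was 5. As many were found in 2.98% of 12096 windows of 101 genes elsewhere, which overlap, so the share is a description. Counted by genotype in the authors' deposited table, Vegf188 had 4 such genes, among them Polh, Mea1 and H2-T24, and 0 of the windows had as many, while Vegf120/188 had 7, as 16.6% of windows did, with Polh in both. Sequence carried along with the modified gene may differ from wildtype there, and a local effect of the modification itself stays open and was not tested.

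In Vegf188 against Vegf120/188, 1 of the 35 splits of the 7 arrays into 4 and 3, the real one, called as many as 8 genes, and the highest of the others called 1. A share of 1 in 35 is the smallest that these splits can give. The adjustment kept the difference of the wildtype and Vegf120/188 means to 8.33e-09 while it raised the SD within groups. Its method is not stated, so the group labels may have entered it. Adjusted arrays could then not be exchanged freely between groups, so the splits do not decide whether chance gave that count. The real split also follows the technical batch, so the splits do not separate batch from genotype. For the 4 lists the splits do not argue against chance, since 14 of the 35 called as many and the highest of the others called 7.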
